A study of Mus musculus with 9 samples.

How the data were processed

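Gene expression was measured by sequencing of polyadenylated RNA, with paired reads of 100 bases, from islets of female mice, in 5 control and 4 STIM1KO libraries, labels that were used as the 2 groups without change. A table of estimated counts per gene, not scaled to library size, was deposited by the authors, and 26.8% to 29.6% of its values per library were not whole numbers (tolerance 1e-06). Each of its 16972 genes had at least 10 estimated counts over the 9 libraries, and the totals per library were between 18.7 and 24.3 on a scale of 1e+06 counts. The second deposited table held log2 CPM without an added offset, in which the authors' library size was 1.49 to 1.75 times the total of the listed genes, and an estimated count of 0 had no value. Per the submitters' processing notes STAR 2.6.1, Partek, DESeq2 and the mm10 genome build were used, with no role or order stated. The annotation, the counting settings and the strand setting are not given in the sources used here.

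Gene names in 22 entries had been turned into dates; these entries were kept in the tests and not named. Coordinates, transcript lengths and GC content were taken from the GENCODE mouse annotation of the mm10 build by gene symbol, and 14265 of the 14541 genes tested (98.1%) had a length. Of the 517 members of the fixed gene lists, counted list by list, 485 were matched by symbol, 2 by an older symbol and 30 were not matched. The 30 that had no match include the members of the lists of mitochondrially encoded and Y-linked genes, which were not analysed here. Counting error at these depths is small against the spread between libraries except for genes with few counts, such as Gper1 and Esr1.

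The estimated counts were rounded, filtered with filterByExpr of edgeR 4.0.16 (R 4.3.3) and normalised with TMM factors. STIM1KO was compared with control by edgeR's quasi-likelihood F-test with robust dispersion (statmod 1.5.0) and no covariate, with Benjamini-Hochberg adjustment over 14541 genes and a threshold of 0.05. Values are log2 fold changes with standard errors, and CPM with SD. Single genes and list levels were also compared by a two-sided exact permutation test over the 126 ways to choose 4 of the 9 libraries, of log2 CPM with 0.5 added for genes; the smallest p it allows is 0.0159. The level of a list in a library is the median deviation of its members from the control mean in log2 CPM (prior count 2).

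A set of 33 gene lists for islet cell types, neighbouring cell types and pathways, the test, the first set of alternatives and the rule for named genes were fixed before the data were examined. Lists with at least 3 members tested, 29 in number, were compared with camera (preset correlation 0.01, and estimated) and fry of limma 3.58.1. The named genes were Stim1, Gper1, Ins1, Ins2, Gcg, Sst, Ppy and Esr1; the 12 largest rises and 12 largest falls among genes that passed, had a mean of at least 1 CPM and kept their sign in each of the 9 fits that leave out a library, without predicted genes and pseudogenes; the 3 smallest adjusted p-values in each direction; and up to 4 members per list that passed, or up to 2 that did not where none passed. Lists of ribosomal protein, proteasome and heat shock genes (3 lists) were added after the data were seen.

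Alternatives chosen at that time were DESeq2 size factors and upper-quartile factors in edgeR, the Wald test of DESeq2 1.42.0, limma-voom, no filter, a filter of 1 CPM in 4 libraries, the fit without robust dispersion, leaving out each library, the replicate number or the description number as a block, an acinar score as covariate, library sizes without hormone and acinar genes, limma on the deposited log2 values, and thresholds of 0.01 and 0.1. Added after the data were seen were offsets per gene and library from a loess fit (span 0.5) on transcript length and GC content, leaving out both libraries of number 311, the number block with these offsets, leaving out each library with these offsets, and library sizes without Rn45s and Lars2. For matched comparisons each list member was set against the 20 genes nearest in length, GC content and expression. The libraries of number 311 were also kept as STIM1KO with each of the 21 pairs of the other 7 libraries put beside them. Libraries were also regrouped in 100 splits of 5 against 4 (random seed 7).

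The test was checked on simulated counts with the fitted dispersions of these libraries. Of 67, 67 and 66 genes changed by 0.58, 1 and 2 on the log2 scale, 56.7%, 88.1% and 98.5% were recovered, with 8 false among 170 calls, and 2 genes were called when none was changed. With the measured length and GC trends added to unchanged genes, 0 were called before or after the offsets. Each gene was drawn independently, with dispersions fitted to libraries that already held these trends. The simulation therefore cannot show how many calls the trends, or other shifts shared by genes, give in the real libraries. There the highest of the other drawn splits gave 1217 genes. No pair of libraries in a group was duplicated: the chi-square per degree of freedom between them was 18.3 to 100.1. Figures and tables were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.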

Results

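RNA was sequenced from hand-picked pancreatic islets of female mice aged 16 weeks that had been fed for 8 weeks on a diet with 60 kcal% fat, and the islets had recovered overnight in medium with 5.5 mM glucose. The 5 control libraries came from mice with a floxed Stim1 gene (Stim1 flanked by sites at which Cre recombinase deletes DNA) and no Cre. The 4 STIM1KO libraries came from floxed mice that also carried Cre in the Ins1 gene, which is active in insulin-producing beta cells. Controls 1 to 5 held 20290807, 24042987, 24211115, 22224440 and 18869793 estimated counts, and STIM1KO libraries 1 to 4 held 22963889, 18694188, 24252636 and 23580581, over 16972 listed genes. The labels also give each library a number whose meaning is not stated. Number 789 was shared by controls 1 to 3 and STIM1KO 3, number 346 by controls 4 and 5 and STIM1KO 4, and number 311 by STIM1KO 1 and 2, with no control. Control 1 and STIM1KO 3 share the letter that follows the number too, and so the code 789N, while the other parts of their descriptions differ. The labels do not state that each library came from a separate animal, and the p-values measure the spread between these libraries.

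The labels imply 1 comparison, which asks how the islet transcriptome differs when beta cells lose Stim1 under a high-fat diet. The series title ties it to the estrogen receptor gene Gper1 and to beta cell dysfunction and dedifferentiation. No control carried Cre, so loss of Stim1 cannot be told apart from Cre itself or its insertion in Ins1. Stim1 encodes the calcium sensor of the endoplasmic reticulum that opens store-operated calcium channels, and it lies on chromosome 7 from 102267806 to 102437319 (mm10). Its level in controls 1 to 5 was 98.8, 93.1, 75.4, 79.6 and 83.3 CPM (counts scaled to the library total), and in STIM1KO libraries 1 to 4 it was 46.1, 44.1, 35.4 and 38.6 CPM. The means were 86.0 ± 9.67 CPM (SD, n = 5) in controls and 41.1 ± 4.88 CPM (SD, n = 4) in STIM1KO islets. Stim1 fell by 1.07 ± 0.11 on the log2 scale (SE), with adjusted p = 0.00146 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and a two-sided exact permutation p of 0.0159, the smallest that 5 against 4 libraries allow. The log2 difference was -1.32 within number 789 and -1.07 within number 346. Islet cells other than beta cells keep Stim1, and the gene-level count includes transcript from outside the floxed exon, so these values check the labels only in part.

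Gper1, which encodes a membrane receptor for estrogen, was detected at a low level in all 9 libraries, with 13 to 46 estimated counts per library (chromosome 5, 139423151 to 139427800). It averaged 1.61 ± 0.617 CPM (SD, n = 5) in controls and 0.948 ± 0.301 CPM (SD, n = 4) in STIM1KO islets. The log2 fold change was -0.73 ± 0.33 (SE), and it did not pass (adjusted p = 0.134 in edgeR's quasi-likelihood test, two-sided exact permutation p = 0.0794). The difference was 0.02 within number 789, -0.87 within number 346 and -0.67 over all 9 libraries on the same scale. In edgeR's test Gper1 had an unadjusted p = 0.0409, and it fell when adjusted over the 7 tested estrogen receptors and responsive genes alone. A difference in Gper1 was therefore not detected with adjustment over all genes, which does not show that the groups were alike. Esr1, the nuclear estrogen receptor alpha gene, had only 2 to 14 estimated counts per library and was removed by the count filter before the test. Its level was 0.277 ± 0.128 CPM (SD, n = 5) in controls and 0.375 ± 0.199 CPM (SD, n = 4) in STIM1KO islets, with an exact permutation p of 0.460.

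**Figure D1:**
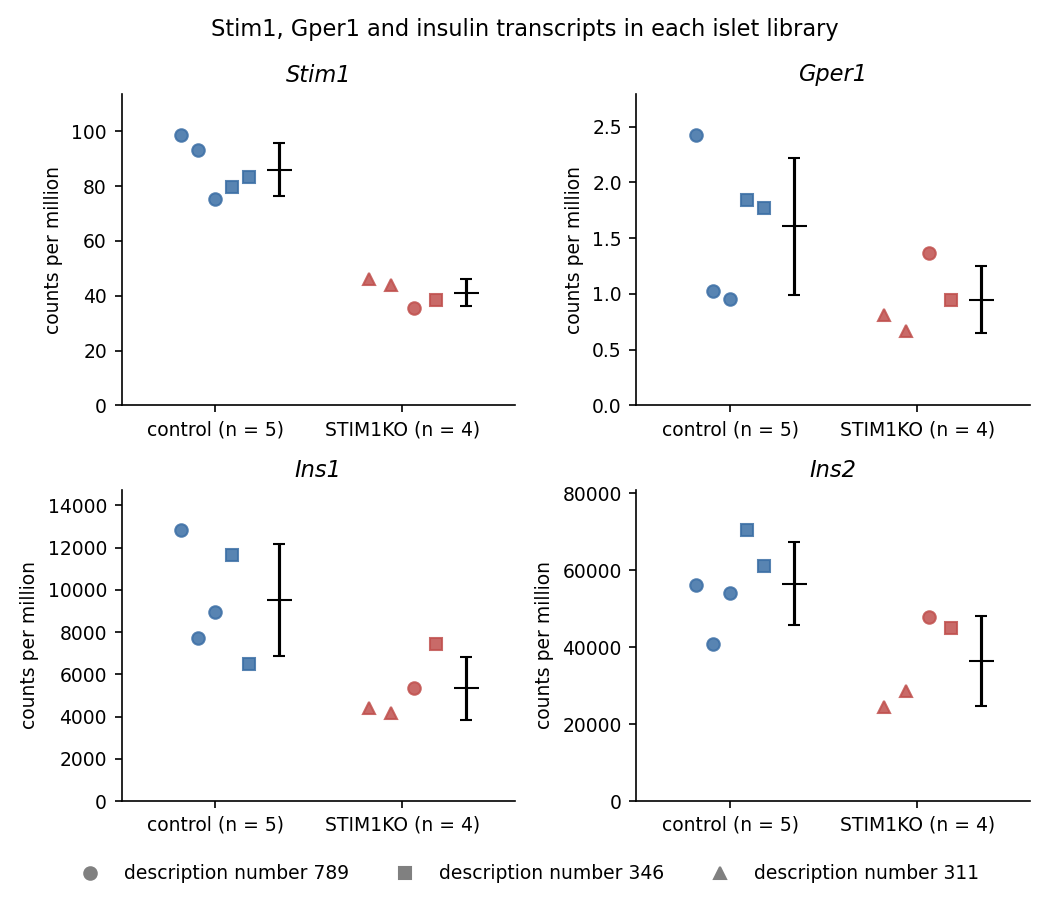
CPM of Stim1, Gper1, Ins1 and Ins2 in each of the 9 islet libraries, with each point a library, the symbol its description number, and the horizontal bar and whiskers the group mean and SD. The 4 STIM1KO libraries lie between 35.4 and 46.1 CPM for Stim1, below all 5 controls, whereas the 2 groups overlap for Gper1, Ins1 and Ins2.

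STIM1KO islets held more transcript of Arid5b, a chromatin-binding regulator of transcription, of the receptor gene Notch1 and of the transcription factor gene Zfhx3. Arid5b rose by 1.06 ± 0.17 on the log2 scale (SE), from 12.0 ± 1.47 CPM (SD, n = 5) to 25 ± 7.41 CPM (SD, n = 4); Notch1 rose by 0.87 ± 0.13 and Zfhx3 by 0.82 ± 0.12. Transcripts that fell included Fdps, which encodes farnesyl diphosphate synthase of the mevalonate pathway, by 0.80 ± 0.13, from 76.6 ± 14.6 to 43.9 ± 2.79 CPM (SD, n = 5 and n = 4). Rpl37, a ribosomal protein gene of the large subunit with sequence-related copies that can share its reads, fell by 0.93 ± 0.15. In edgeR's quasi-likelihood test each of these 5 genes had adjusted p = 0.0191, and in all of them the 2 groups did not overlap. They were chosen by their small p, so the lack of overlap adds no support. Without both libraries of number 311 Arid5b, Notch1, Fdps and Rpl37 were at 0.79, 0.70, -0.76 and -0.81 and did not pass (adjusted p = 0.316 for each in edgeR). After offsets for transcript length and GC content Notch1 and Rpl37 passed at 0.40 and -0.60, and Zfhx3, at 0.31, did not. In mm10 coordinates Arid5b lies on chromosome 10 from 68092520 to 68278740, Notch1 on chromosome 2 from 26457903 to 26516663, Zfhx3 on chromosome 8 from 107942644 to 108961630, Fdps on chromosome 3 from 89093588 to 89101959 and Rpl37 on chromosome 15 from 5116645 to 5119140.

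Among the genes admitted by the rule for named genes, which asks for a mean of at least 1 CPM and leaves out predicted genes, the largest rise was that of Adamts4, a secreted protease gene, at 1.66 ± 0.35 on the log2 scale (2.36 ± 0.566 CPM in controls, n = 5, and 7.47 ± 4.22 CPM in STIM1KO, n = 4, SD). It was followed by Sox7, an endothelial transcription factor gene, at 1.51 ± 0.36, Ldb2 at 1.39 ± 0.41 and Flt1, a receptor gene for vascular endothelial growth factor, at 1.38 ± 0.36. The potassium channel gene Kcnh1 rose by 1.35 ± 0.36, Cyyr1 by 1.32 ± 0.30, the basement membrane gene Nid2 by 1.21 ± 0.28 and the semaphorin co-receptor gene Plxna4 by 1.2 ± 0.25. Myo1f, Plekhg1, Flt4 and Adam19 rose by 1.18 to 1.19. The largest fall among them was that of the chemokine gene Cxcl1, at -1.21 ± 0.35, while 2610037D02Rik, which the rule left out and which was chosen after its values were seen, fell by 2.03 ± 0.42. After Stim1 came Mvd at -1.04 ± 0.27, Lzts1 at -1.02 ± 0.27 and Msmo1 at -1.01 ± 0.23, of which Mvd and Msmo1 encode enzymes of sterol synthesis. Acat2, Dpm1, Cst6, Cyp51, Hsd17b7 and Plau fell by 0.90 to 0.96, and among them Acat2, Cyp51 and Hsd17b7 also act in sterol synthesis. Without the libraries of number 311, the fold changes of Adamts4, Sox7, Ldb2, Flt1 and Kcnh1 were 0.70, 0.50, 0.51, 0.59 and 0.48, those of Cyyr1, Nid2, Plxna4, Plekhg1 and Flt4 were 0.64 to 0.77, and those of Mvd and Msmo1 were -1.08 and -0.84. With the length and GC offsets Flt1 (1.08), Kcnh1 (1.01), Plxna4 (0.74), Myo1f (1.01), Cxcl1 (-0.89), Mvd (-1.05), Cyp51 (-0.94), Hsd17b7 (-0.90) and Plau (-0.82) did not pass. Of the 65 named genes that passed, 62 had the same sign within number 789 and within number 346, the exceptions being Angptl4, Pdia4 and Tie1. These genes had passed in a fit that included the same libraries, and each of the 2 numbers holds 1 STIM1KO library. The shared sign is thus no independent support.

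Across the 14541 genes tested, edgeR's quasi-likelihood test called 2071 at an adjusted p under 0.05, of which 975 were higher and 1096 lower in STIM1KO islets; 67 of them changed at least 2-fold, 57 higher and 10 lower. The groups did not overlap in CPM for 1802 genes (12.39%). Chance gives 1.59% if the libraries are exchangeable, which is in doubt because number 311 holds no control. The count rested on particular libraries: it was 2 without both libraries of number 311 (Slc15a2, which lies outside the rule for named genes and was chosen after its values were seen, and Stim1) and 2 with the description number as a block, against 2112 and 2198 genes at an unadjusted p under 0.05. It was 1 (Stim1) without control 4, STIM1KO 1 or STIM1KO 2, with 3704, 3611 and 3605 genes at an unadjusted p under 0.05, and 992, 927, 3616 and 647 without control 3, control 5, STIM1KO 3 and STIM1KO 4. On all 9 libraries DESeq2 called 3058 genes and limma-voom 2047. The share of called genes that were higher was 47.1%, against 62.9% of 1074 genes with limma on the deposited log2 CPM and 25.8% of 886 genes after offsets for transcript length and GC content.

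Fold changes also ran with transcript length. The median log2 fold change was -0.33 in the shortest decile of the genes, where 387 genes were called lower and 2 higher, and 0.26 in the longest decile, where 330 were called higher and 15 lower. Spearman's rho between fold change and transcript length was 0.458 across genes, which are not independent replicates. Measured library by library, the rho of a gene's deviation with length averaged -0.226 ± 0.234 (SD, n = 5) in controls and 0.284 ± 0.107 (SD, n = 4) in STIM1KO libraries, and the 2 sets did not overlap (exact permutation p = 0.0159).

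**Figure D2:**
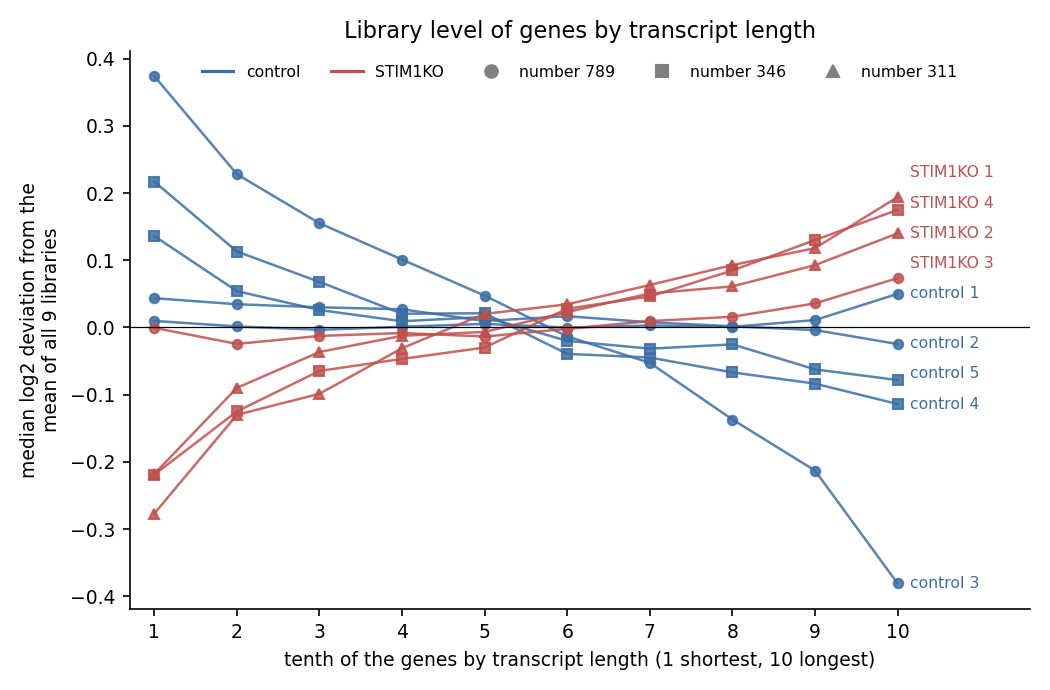
Median log2 deviation of genes from their mean over all 9 libraries, for each library (line; colour, group; symbol, description number), against the decile of the genes by transcript length from the shortest (1) to the longest (10). In the longest decile the 4 STIM1KO libraries lie between 0.0734 and 0.194 and the controls between -0.381 and 0.05.

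Gene lists fixed before the data were examined were then compared. Nuclear-encoded subunits of oxidative phosphorylation, the respiratory chain and ATP synthase of mitochondria, were lower in STIM1KO islets: 20 of the 29 members tested fell, 0 rose and 9 did not pass, and 26 fell when adjusted over the list alone. Ndufa2, a subunit of complex I, fell by 0.71 ± 0.14 on the log2 scale, Cox7a2 and Cox5a, subunits of cytochrome c oxidase, fell by 0.64 ± 0.13 and 0.57 ± 0.10, and Ndufb5 of complex I fell by 0.63 ± 0.13. The median deviation of the members from the control mean was -0.533, -0.489, -0.244 and -0.501 in STIM1KO libraries 1 to 4, and lay between -0.109 and 0.174 in controls (exact permutation p = 0.0159, 0.197 adjusted over 29 lists). Within number 789 the difference was -0.23 and within number 346 it was -0.51, against -0.44 over all 9 libraries. Limma's camera gave the list adjusted p = 6.1e-12 at a preset correlation of 0.01 and adjusted p = 0.909 with an estimated correlation; limma's fry gave adjusted p = 0.0190. The members were short, with a median transcript length of 1482.5 bases against 3135 over all genes tested. After offsets for length and GC content 10 members fell, with Ndufa2, Cox7a2 and Ndufb5 at -0.33, -0.29 and -0.36, whereas Cox5a, at -0.19, did not pass. Relative to genes matched on length, GC content and expression the list differed by -0.12 on the log2 scale (exact permutation p = 0.0159). The 20 calls became 12 without control 3 or control 5, 9 without STIM1KO 4 and 0 without control 4, STIM1KO 1, STIM1KO 2 or both libraries of number 311, where the median log2 fold change was -0.35.

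Of the 20 cholesterol synthesis genes tested, 5 fell, 0 rose and 15 did not pass, and 16 fell when adjusted over the list alone. Besides Fdps, Mvd, Msmo1 and Cyp51, the fall was seen in Sc5d, a sterol desaturase gene, at -0.61 ± 0.14. The list's level was between -0.827 and -0.521 in the STIM1KO libraries, and controls 2 and 3, at -0.476 and -0.603, lay near or within that range while controls 1, 4 and 5 lay between 0.229 and 0.537. Within number 789 the difference was -0.30 and within number 346 it was -0.92. Camera gave adjusted p = 1.2e-05, adjusted p = 0.909 with an estimated correlation, and fry gave adjusted p = 0.167. The 5 calls became 13 and 12 without control 2 and control 3, 3 and 2 without control 5 and STIM1KO 4, and 0 without control 4, STIM1KO 1, STIM1KO 2 or both libraries of number 311, where the list's median log2 fold change was -0.61 against -0.63 over all 9 libraries; Fdps, Msmo1 and Sc5d fell after the length and GC offsets.

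Endothelial cell markers were higher: 7 of 14 members rose, 0 fell and 7 did not pass, and 9 rose when adjusted over the list alone. Besides Flt1, the receptor genes Kdr, Robo4 and Tie1 rose by 0.74 ± 0.16, 0.79 ± 0.19 and 0.79 ± 0.22, and the endoglin gene Eng by 0.66 ± 0.15. The list's level was highest in the libraries of number 311, at 1.16 and 0.907, against 0.0672 and 0.380 in STIM1KO 3 and 4 and -0.155 to 0.162 in controls. The difference was 0.14 within number 789 and 0.25 within number 346, against 0.62 over all 9 libraries. Without both libraries of number 311 the list's median log2 fold change was 0.22 rather than 0.70, with Kdr, Robo4, Tie1 and Eng at 0.30 to 0.36, and 0 members passed. Camera gave adjusted p = 0.0013, adjusted p = 0.909 with an estimated correlation, and fry gave adjusted p = 0.167. The 7 calls became 4 without control 1, control 2 or STIM1KO 4, 3 without control 3 or control 5, and 0 without control 4, STIM1KO 1 or STIM1KO 2 or after the length and GC offsets. With the offsets the list's median was 0.49 and Kdr, for example, had 0.51 ± 0.14 (adjusted p = 0.0516 in edgeR), a smaller fold at a similar SE; Robo4, Tie1 and Eng had 0.51, 0.51 and 0.45. Tie1 was -0.07 within number 789.

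Markers of fibroblasts, stellate cells and pericytes included 3 genes that rose, 0 that fell and 11 that did not pass among 14 tested, and 4 rose when adjusted over the list alone. Pdgfrb, a pericyte receptor gene, rose by 0.55 ± 0.12, the matrix genes Sparc and Col3a1 by 0.54 ± 0.12 and 0.51 ± 0.15. After the length and GC offsets Sparc alone rose (0.57), and Pdgfrb and Col3a1 did not pass in edgeR, both at 0.26 (adjusted p = 0.213 and 0.278). The difference was 0.73 within number 789 and 0.12 within number 346. Camera gave adjusted p = 0.05 (under the threshold before rounding), adjusted p = 0.909 with an estimated correlation, and fry gave adjusted p = 0.124. Of the macrophage markers, 1 of 14 rose, Cd68 at 0.56 ± 0.16, and of the duct cell markers 1 of 11, Hnf1b, with the same counts adjusted over the list alone; after the length and GC offsets the duct marker Krt7, chosen after its values were seen, also fell. Without number 311 Cd68 was 0.22 and Hnf1b 0.34, and neither passed; Cd68 was at 38.3 and 25.8 CPM in the libraries of number 311 and at 20.3 and 21.3 CPM in STIM1KO 3 and 4. No acinar marker of 23 and no Schwann cell marker of 6 passed in edgeR's test, also adjusted over the list alone. The only lymphocyte marker above the count filter, Cd79a, had a log2 fold change of -0.16 ± 0.31 and did not pass, and 0 erythroid markers were above it. The acinar markers differed with the description number instead: their level was 1.44, 2.39 and 1.01 in control 4, control 5 and STIM1KO 4, the libraries of number 346, and between -1.71 and 0.0407 in the other 6.

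**Figure D3:**
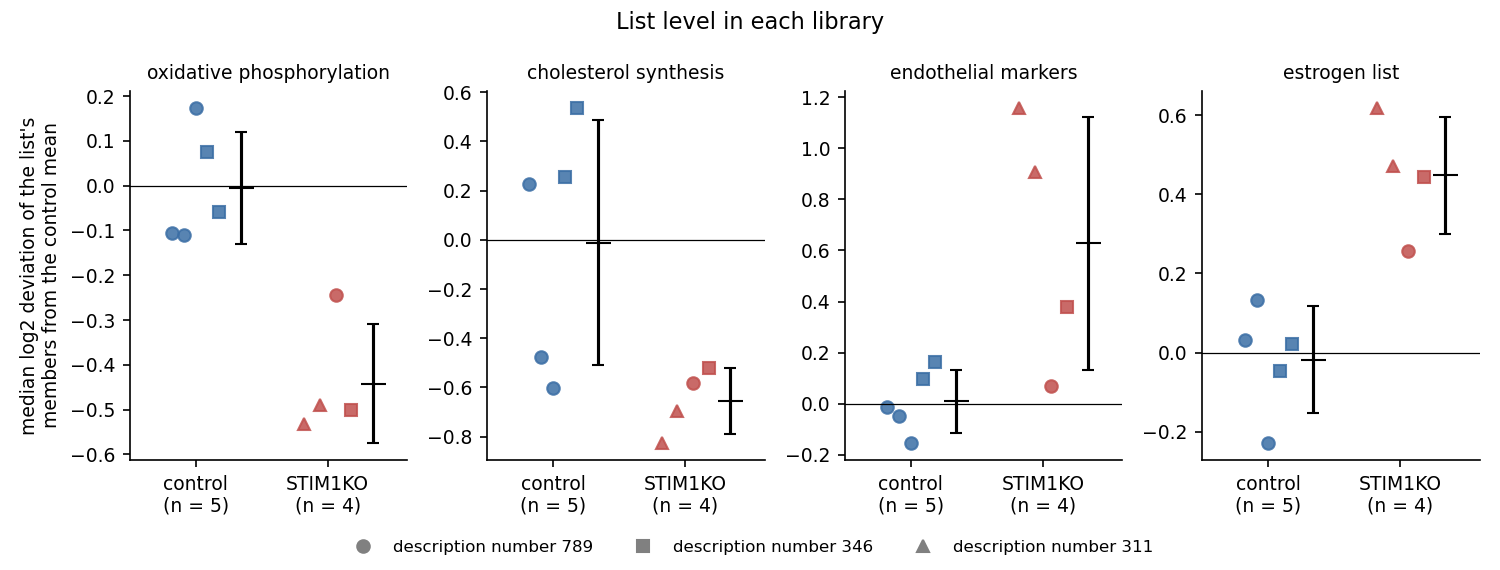
Median log2 deviation of a list's members from the control mean in each of the 9 islet libraries, for the oxidative phosphorylation, cholesterol synthesis, endothelial and estrogen lists; points are libraries, symbols their description numbers, and the bar and whiskers the group mean and SD. The 2 libraries of number 311 lie at 1.16 and 0.907 for the endothelial markers, above STIM1KO 3 and 4 at 0.0672 and 0.380.

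Among estrogen receptors and responsive genes, Nrip1, a corepressor of nuclear receptors, rose by 0.70 ± 0.14, from 44.1 ± 8.42 CPM (SD, n = 5) to 71.8 ± 12.6 CPM (SD, n = 4), and Ncoa3, a nuclear receptor coactivator, rose by 0.53 ± 0.13. These were 2 of the 7 members tested, while 0 fell and 5 did not pass. Adjusted over the list alone 5 rose and 1, Gper1, fell. The list's level was 0.619, 0.472, 0.258 and 0.443 in STIM1KO libraries 1 to 4 and between -0.229 and 0.133 in controls (exact permutation p = 0.0159, 0.197 adjusted over 29 lists). The difference was 0.28 within number 789 and 0.46 within number 346. Camera gave adjusted p = 0.0279, adjusted p = 0.721 with an estimated correlation, and fry gave adjusted p = 0.0155. After the length and GC offsets Nrip1 alone passed and Ncoa3 was 0.23; Ncoa3 was 0.35 without number 311, and 0 members passed without control 4, STIM1KO 1, STIM1KO 2 or both libraries of number 311, while the list's median log2 fold change, 0.53 over all 9 libraries, was 0.35 with the offsets and 0.35 without number 311.

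Of the insulin genes, Ins1 (chromosome 19, 52264297 to 52265476) fell by 0.83 ± 0.22 on the log2 scale, from 9527 ± 2654 CPM (SD, n = 5) to 5344 ± 1500 CPM (SD, n = 4), with adjusted p = 0.0297 in edgeR's test. Ins2 (chromosome 7, 142678656 to 142743381) had 56552 ± 10745 CPM in controls and 36453 ± 11618 CPM in STIM1KO islets, a log2 fold change of -0.63 ± 0.20 that did not pass in edgeR's test (adjusted p = 0.0513). The 2 genes are similar enough to share reads, so the split between them is uncertain. Ins1 also holds the Cre insertion in STIM1KO mice, which cannot be told apart from Stim1 loss as a source of its fall. Iapp, which encodes the amyloid peptide released with insulin, fell by 0.64 ± 0.14 (adjusted p = 0.0201 in edgeR's test). Within numbers 789 and 346 the differences were -0.84 and -0.22 for Ins1, -0.06 and -0.55 for Ins2, and -0.27 and -0.70 for Iapp. Without both libraries of number 311 they were -0.57, -0.29 and -0.47, and none of the 3 genes passed. In edgeR with the length and GC offsets Ins1 did not pass (-0.57, adjusted p = 0.219) and Iapp passed at -0.32.

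Ins1 and Iapp were 2 of the 30 beta cell maturity and function genes tested; 0 rose and 28 did not pass, Iapp alone fell with the offsets, and 1 rose and 4 fell when adjusted over the list alone. Among beta cell transcription factors, Tcf7l2, the effector of Wnt signalling, rose by 0.64 ± 0.17 (0.37 without number 311, not passing) and the other 18 of 19 did not pass, while 9 rose and 2 fell when adjusted over the list alone. Mafa, Pdx1 and Nkx6-1, chosen after their values were seen, had log2 fold changes of -0.71, 0.05 and 0.37 and did not pass. Of 11 dedifferentiation and progenitor genes, Hnf1b, a progenitor and duct transcription factor gene, rose by 0.54 ± 0.13 and 10 did not pass, with 1 rising when adjusted over the list alone. In the same list Aldh1a3, a marker of dedifferentiated beta cells, had a log2 fold change of -0.01 and Neurog3, the endocrine progenitor factor, of -0.58 (adjusted p = 0.0676 in edgeR's test); both were chosen after their values were seen. Of 20 genes normally repressed in beta cells, 0 passed, also when adjusted over the list alone; Hk1 and Slc16a1 had log2 fold changes of 0.83 ± 0.27 and -0.63 ± 0.25. Hk1, at 34.5 and 17.3 CPM in the libraries of number 311 and 12.7 and 12.5 CPM in STIM1KO 3 and 4, was 0.22 without number 311. Limma's camera called none of these 4 lists, with adjusted p = 0.140, 0.0739, 0.963 and 0.683. Without control 1 or STIM1KO 3, 6 and 7 of the beta cell transcription factors rose, and without STIM1KO 3, 7 of the maturity genes fell.

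Hormone transcripts of the other islet cells did not pass. In edgeR's test Gcg, the glucagon gene of alpha cells, had a log2 fold change of -0.30 ± 0.15 (adjusted p = 0.169), Sst of delta cells 0.23 ± 0.13 (adjusted p = 0.246) and Ppy of PP cells -0.39 ± 0.59 (adjusted p = 0.683). Gcg was -0.03 with the length and GC offsets, -0.05 without number 311, and -0.03 and -0.07 within numbers 789 and 346; without number 311 Sst was 0.08. After the length and GC offsets Sst and the delta cell transcription factor gene Hhex passed in edgeR, with rises of 0.54 and 0.56 (adjusted p = 0.0399 and 0.0382), and Ppy turned to 0.04. Of 14 alpha cell markers and of 8 delta and PP cell markers 0 passed without the offsets over all genes or adjusted over the list alone. Gc and Irx2 had -0.33 ± 0.11 and -0.49 ± 0.17, and Hhex and Rbp4 had 0.41 ± 0.15 and -0.38 ± 0.14. With the offsets Gc, Irx2 and Rbp4 were -0.15, -0.58 and -0.19. The alpha list's level was -0.374 and -0.531 in the libraries of number 311 and 0.0025 and 0.0011 in STIM1KO 3 and 4. Its median log2 fold change was -0.24 over all 9 libraries and 0.04 without number 311.

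Of 16 genes of store-operated calcium entry and endoplasmic reticulum calcium handling, Stim1 and Saraf fell, 0 rose and 14 did not pass, with the same counts adjusted over the list alone. Saraf, which inactivates store-operated calcium entry, fell by 0.41 ± 0.10. Saraf passed at -0.32 with the length and GC offsets, and without number 311 it was -0.30 and did not pass. Insulin exocytosis and excitability genes included 3 that rose among 19, the calcium channel gene Cacna1a by 0.54 ± 0.14, Stxbp1 of the fusion machinery by 0.43 ± 0.12 and the vesicle-priming gene Unc13a by 0.60 ± 0.17. None of them fell, 16 did not pass and 6 rose when adjusted over the list alone. Camera gave adjusted p = 0.0469, adjusted p = 0.909 with an estimated correlation, and fry gave adjusted p = 0.183. After the length and GC offsets 0 of the 19 passed (median log2 fold change 0.07 against 0.15), and 0 without control 3, control 4, STIM1KO 1, STIM1KO 2 or both libraries of number 311 (0.19); 1 rose without control 5 or STIM1KO 4 and 6 without control 1 or STIM1KO 3. Stxbp1, Cacna1a and Unc13a were 0.27, 0.10 and 0.15 with the offsets, and Unc13a was 0.28 without number 311.

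Antioxidant genes included 4 that fell, 0 that rose and 11 that did not pass among 15, and 7 fell when adjusted over the list alone. Txn1, the thioredoxin gene, fell by 0.73 ± 0.14, the peroxiredoxin gene Prdx1 by 0.55 ± 0.14, Gpx1 of glutathione peroxidase by 0.45 ± 0.11 and Sod2 of mitochondrial superoxide dismutase by 0.34 ± 0.10 (limma's camera, adjusted p = 0.0617). In the unfolded protein response list 4 of 25 fell and 21 did not pass, with the same 4 adjusted over the list alone. These were the chaperone gene Hspa5 at -0.40 ± 0.11, Manf at -0.41 ± 0.12, Asns of asparagine synthesis at -0.40 ± 0.11 and the disulfide isomerase gene Pdia4 at -0.37 ± 0.12 (limma's camera, adjusted p = 0.617). With the offsets Gpx1 (-0.26) and Pdia4 (-0.28) did not pass, and Txn1 and Asns passed at -0.45 and -0.27; within number 789 the differences of Pdia4, Hspa5, Manf, Asns, Prdx1 and Sod2 were 0.0058, -0.06, -0.04, -0.12, -0.10 and -0.07, and within number 346 they were -0.44 to -0.75. The antioxidant count was 7 without control 2 or STIM1KO 3 and 1 without control 5 or STIM1KO 4. In the NF-kB list Cxcl1 and the inhibitor gene Nfkbia (-0.47 ± 0.12) fell and 11 of 13 did not pass. Among apoptosis regulators Apaf1 of the apoptosome rose by 0.56 ± 0.14, Bax fell by 0.42 ± 0.09 and 13 of 15 did not pass. Angptl4, a lipase inhibitor gene, rose by 1.44 ± 0.39 at 0.426 ± 0.141 and 1.16 ± 0.584 CPM (SD, n = 5 and n = 4) and was 1 of 14 fatty acid synthesis and oxidation genes. It was 0.72 without number 311, where it did not pass, and 1.2 and -0.07 within numbers 789 and 346. Pcna fell by 0.53 ± 0.12 among 16 cell cycle genes and Hilpda by 0.86 ± 0.22 among 11 hypoxia response genes, with the other members not passing. After the length and GC offsets 0 members of the NF-kB, apoptosis and hypoxia lists passed, with Cxcl1, Nfkbia, Apaf1, Bax and Hilpda at -0.89, -0.33, 0.40, -0.19 and -0.57, and Pcna passed at -0.32. For these last 5 lists the counts adjusted over the list alone were the same. Of 14 immediate early, 11 calcineurin and NFAT, 14 glycolysis, 12 cell cycle inhibitor and senescence and 19 interferon and antigen presentation genes, 0 passed over all genes or adjusted over the list alone. Limma's camera called none of these 5 lists (adjusted p from 0.109 to 0.961). The level of the glycolysis list was 1.05 and 0.546 in the libraries of number 311 and between -0.237 and 0.0838 in the other 7. Without control 3, control 5 or STIM1KO 4, 0 members of the unfolded protein response and NF-kB lists passed.

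**Figure D4:**
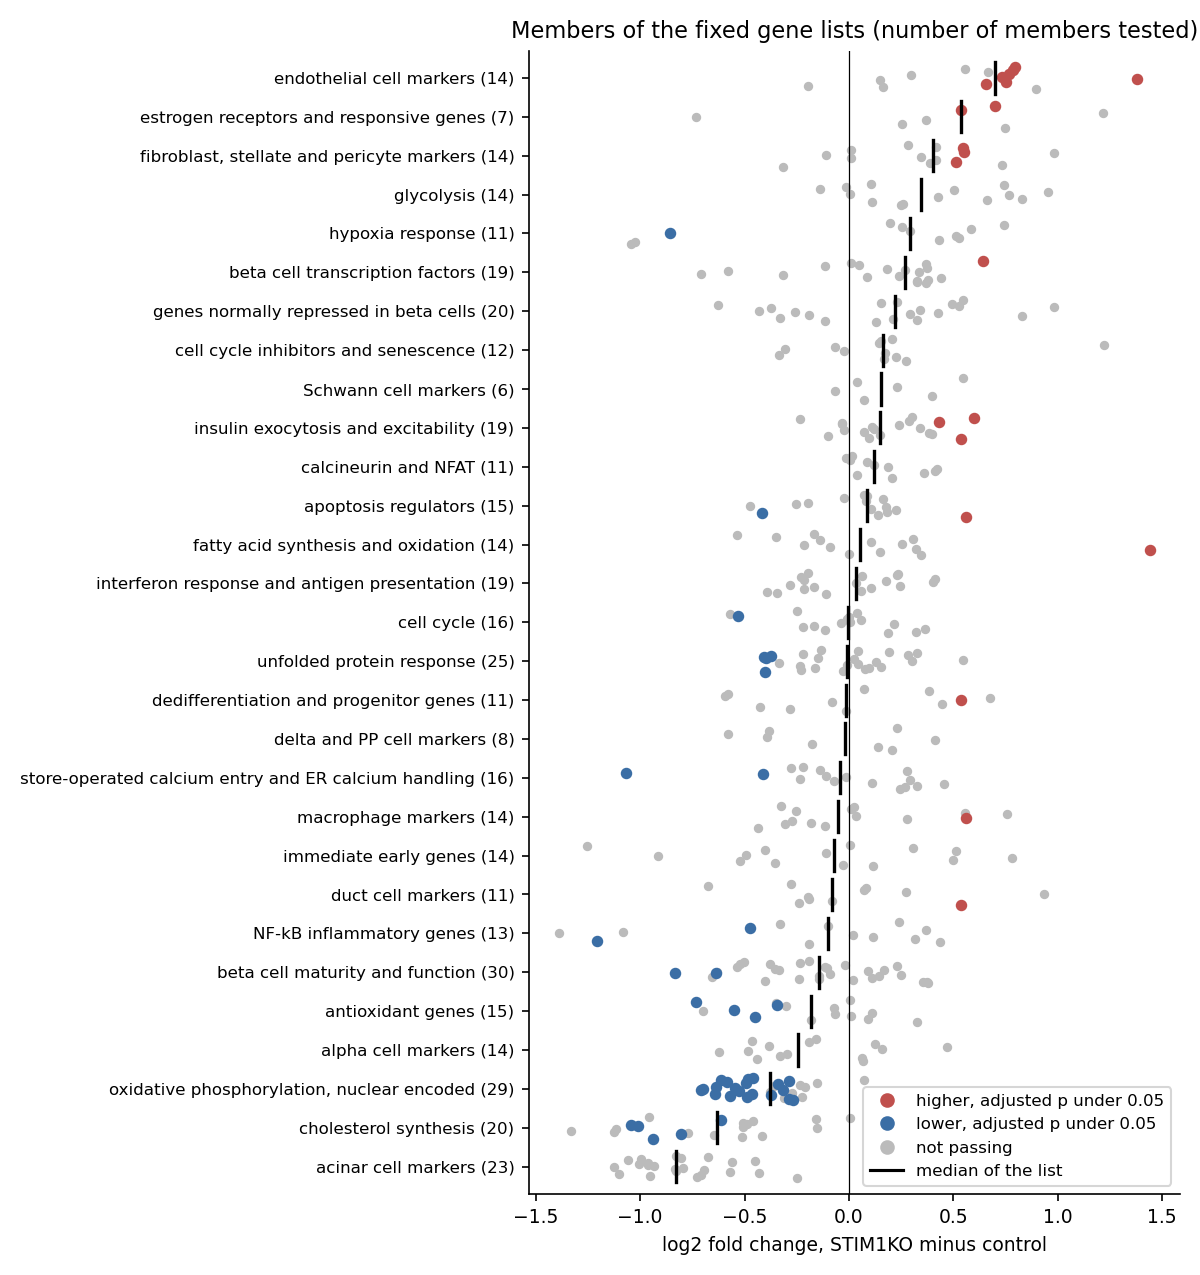
Log2 fold change (STIM1KO minus control) of each tested member of the 29 fixed gene lists in the edgeR fit of all 9 islet libraries, with the number of members in brackets, red and blue points for members higher and lower at an adjusted p under 0.05, grey for those not passing and a vertical bar for the list's median. The oxidative phosphorylation list has 20 members lower and 0 higher, and the endothelial list 7 higher and 0 lower.

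Camera at the preset correlation called 6 of the 29 lists and 0 with an estimated correlation, whereas fry, which tests whether a list's members move one way without comparing them with other genes, called 2, the oxidative phosphorylation and estrogen lists. List medians, means and camera directions differed in sign where the medians and means lay between -0.08 and 0.03, in the dedifferentiation, delta and PP, duct, macrophage and interferon lists. Leaving out control 4, STIM1KO 1 or STIM1KO 2 left 0 members passing in each list other than that of calcium handling, where Stim1 passed. In the 10 lists with 0 members passing in edgeR's test, 22 of 139 genes had an unadjusted p under 0.05, DESeq2 called 9 and limma-voom 0. Of the 64 named genes besides Stim1 that passed, 42, 40 and 39 passed without control 3, control 5 and STIM1KO 4, and 36 after the length and GC offsets, where Zfhx3 (0.31), Cacna1a (0.10) and Unc13a (0.15) were among those that did not.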

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

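Every test of an explanation below was chosen after the result it addresses had been seen. Of 264 sets of 4 or 5 values tested for a library far from the others of its group, 14 held one, where chance gives about 1 in 20 or 13.2, and 7 of the 14 lay in STIM1KO 3. STIM1KO 3 was the highest of its group for the oxidative phosphorylation list at -0.244, the proteasome list at -0.217 and the ribosomal protein list at -0.219 (median log2 deviation from the control mean), where the next libraries were at -0.489, -0.444 and -0.55. It was also highest for Pcna at 45 CPM, Pdia4 at 397, Plau at 10.3 and Rbp4 at 188 CPM. Control 2 was the highest control for Nrip1 at 58.7 CPM and Stat1 at 45.5 CPM, and the lowest for the immediate early genes at -1.07. Control 3 was the lowest control for Plxna4 at 2.36 CPM and the highest for the apoptosis list at 0.116, and STIM1KO 1 was the highest of its group for Adam19 at 5.84 CPM and the lowest for Cox5a at 20.1 CPM.

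The number of genes called between STIM1KO and control islets, 2071, was reached by 1 of 100 drawn splits of the libraries, the real one. The highest of the other drawn splits gave 1217. The count was thus unusual among drawn splits made without regard to the description number. That does not exclude chance, because number 311 holds no control and the libraries are not freely exchangeable. Of the 12 splits that keep each number's group sizes, 2 gave 2071 or more, the real one and the exchange of control 1 and STIM1KO 3, and 12 splits are too few for a share under 0.05; with the number as a block 2 genes passed. That exchange, a split that was not drawn, gave 2319 genes with an adjusted p of 0.478 for Stim1 in edgeR; a real exchange of these libraries, which share a code in the labels, is argued against by Stim1, which was 35.4 CPM in STIM1KO 3, under all 5 controls. For the lists called by camera chance cannot be excluded, since 63 of the 100 splits gave 6 or more and the highest other gave 17. Without both libraries of number 311 edgeR called 2 of 14836 genes, but the 2071 genes kept their sign, with a median size of the log2 fold change of 0.373 against 0.484, which does not decide, since with control 1 in the place of STIM1KO 3 the 2319 genes called also kept theirs (100%, 0.347 against 0.447). With number 311 kept as STIM1KO, 2 of the 21 pairs of the other 7 libraries, the real one included, gave 2071 genes or more, while each of the 10 pairs of controls gave 0 in edgeR (253 to 1567 genes at an unadjusted p under 0.05). A difference of the libraries of number 311 other than genotype cannot be told apart from an effect of Stim1 loss for most calls, because number 311 holds no control. The pairs do not decide it. The other pair that gave 2071 genes or more, control 1 and STIM1KO 4, itself held a STIM1KO library. The pairs of controls left STIM1KO 3 and 4 in the control group.

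The lower oxidative phosphorylation transcripts were tested against the length and GC trend of the libraries and against number 311: genes matched on length, GC content and expression differed by -0.297 on the log2 scale themselves, and the members differed from them by a further -0.122. The exact permutation p of that difference was 0.0159, the smallest the test allows, without adjustment over lists. It does not decide whether the trend alone is the whole cause, because the libraries are not freely exchangeable. The calcineurin and NFAT list, of which 0 members passed, reached the same p, and STIM1KO 4 at -0.0766 lay close to control 5 at -0.0689. With the description number as a block limma's fry gave an unadjusted p = 0.0226, which argues against number 311 alone as the whole cause. That fry test used values without the offsets, so the trend and number 311 were not tested together for the list. Relative to matched genes the list was at -0.242, -0.0881, -0.0992 and -0.0766 in STIM1KO 1 to 4, and at -0.0689 to 0.0367 in controls. The trend could account for part or all of the fall, since the matched genes moved too. Without number 311 the list's median log2 fold change was -0.35 against -0.38, so the 20 calls ended there with the fold about as large and 7 libraries left. A lower level of these transcripts after Stim1 loss in beta cells remains a hypothesis, found and tested on the same libraries.

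The higher endothelial markers lay in the libraries of number 311, at 0.949 and 0.7 above genes matched on length, GC content and expression. The other 7 libraries were at -0.139 to 0.19. The matched genes moved by 0.0936 between the groups, and were at 0.0469 and 0.17 in STIM1KO 1 and 2. In these 2 libraries the matched genes thus shared little of the rise. The 2 were singled out because the list was highest there, so their values do not decide whether the length trend is the whole cause. Nor does the exact permutation test over all 9 libraries. Over all 9 libraries the difference from matched genes was 0.437, with an exact permutation p of 0.0952, and with the number as a block limma's fry gave p = 0.195. The median log2 fold change was 0.22 without number 311 against 0.70 with it, so a difference of number 311 cannot be told apart from the genotype with 2 other STIM1KO libraries. In both libraries of number 311, 13 of the 14 markers lay above the control mean, with Emcn at 0.0123 and -0.491 as the exception. A larger share of endothelial cells in these libraries may be a source, and the abundant markers Kdr and Flt1 were higher there by 1.17 and 2.22 in STIM1KO 1, but Emcn and Esam (0.359) moved less, and hand-picking does not remove vessels inside islets.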

How the results depend on the processing

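The alternatives with offsets, those without both libraries of number 311 and that without Rn45s and Lars2 were chosen after seeing the data. Stim1 in STIM1KO against control stayed lower and passed in all 36 alternatives, with log2 fold changes from -1.38 to -1.01, and Gper1 in STIM1KO against control stayed lower and did not pass in all 35 with a value, from -1.07 to -0.45 with adjusted p from 0.0615 to 0.651; DESeq2's filter gave it no adjusted p. Of the 2071 called genes, 2049 to 2071 were tested in each alternative without offsets and all of these kept their sign, and 2021 of 2047 kept it with the offsets. The totals with other factors, filters, library sizes and count tools, and without robust dispersion, ran from 1934 to 3058, and the acinar covariate gave 1868. The cause of the changes below was not tested, apart from the effect of the threshold itself. Fewer libraries alone do not account for the counts with a library left out, which ran from 1 without control 4 to 3616 without STIM1KO 3.

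Leaving out each library gave 1 to 3616 genes, 0 to 1540 higher and 1 to 2076 lower. It gave 992, 1, 927, 1, 1, 3616 and 647 without control 3, control 4, control 5 and STIM1KO 1, 2, 3 and 4. With the description number as a block 2 genes passed, 0 higher and 2 lower, and the same numbers held without both libraries of number 311. Limma on the deposited log2 values gave 1074 genes, 398 of them lower, and the length and GC offsets gave 886, with 229 higher and 657 lower. With the number block and the offsets 1 gene passed, 0 higher and 1 lower. An adjusted p under 0.01 gave 1 gene, 0 higher and 1 lower, and under 0.1 it gave 3659, 1740 higher and 1919 lower. With the offsets and without a library the counts were 1078 genes (332 higher) without control 2, 1763 (625 higher) without STIM1KO 3, and 2, 4 and 3 genes, all lower, without control 1, 3 and 5, and 1 gene, lower, without control 4, STIM1KO 1, 2 or 4. Only Stim1 passed in each of the 9 fits that left out a library, and 520 genes passed in the 6 that kept control 4, STIM1KO 1 and STIM1KO 2. In edgeR the fits with 0 or few genes had 1759 to 4791 at an unadjusted p under 0.05. The replicate number as a block gave 2630 genes, 1194 higher and 1436 lower, but the numbers do not pair the libraries: STIM1KO libraries correlated with the control of their number at 0.0481, -0.0511, 0.373 and -0.0424 and 3 of 4 correlated best with another control.

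Camera called 6 lists, 0 with an estimated correlation, 3 with the stricter filter, 3 to 7 when a library was left out (3 without control 3 or STIM1KO 3), and 3 with the offsets and without control 1, 2 or 3 or STIM1KO 3. The reversed genes did not pass before or after, except Unc13a, which passed before. The Cd79a log2 fold change was -0.41 to 0.12 with each library left out, and with the offsets 0.13 without control 3 and 0.25 without STIM1KO 4. Gcg was 0.14 with the number block and offsets, and with the offsets 0.10 without control 1, 0.012 without STIM1KO 1 and 0.040 without STIM1KO 2. The Gfap log2 fold change was -0.030 to 0.89 with each library left out and -0.086 with the offsets without STIM1KO 1. Gpi1 was -0.051 with the number block, -0.043 without number 311 and -0.082 with block and offsets. Ppy was 0.046 with the replicate block, 0.039 with the offsets, 0.11 with number block and offsets, and with the offsets 0.31, 0.066, 0.21, 0.18 and 0.16 without control 3, 4 and 5 and STIM1KO 2 and 4. Spink1 was 0.17 with the offsets without control 5, and Unc13a -0.11 with number block and offsets. Genes with few counts, such as Gper1 with 13 to 46 and Esr1 with 2 to 14 per library, have the largest counting error.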

Other observations

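Every list and test in the next paragraphs was chosen after the data had been seen. Ribosomal protein genes were lower in STIM1KO islets: 63 of 82 tested fell and 0 rose, where 6.18 lower would be drawn by chance from genes of any length (Fisher's exact test, one-sided p = 1.69e-54, genes not being independent). Of the proteasome subunit genes 22 of 37 fell and 0 rose, against 2.79 by chance (p = 5.1e-16, one-sided Fisher's exact test). These p-values add no support, since the lists were formed after the falls were seen and their members are short. In the shortest decile 387 of 1427 genes were called lower. Genes matched on length, GC content and expression differed by -0.365 and -0.276, against -0.471 and -0.403 for the 2 lists, and the members differed from them by -0.117 and -0.135. Adjusted over the list alone 77 and 31 fell. Limma's camera gave adjusted p = 0.161 for both with an estimated correlation. The list levels were -0.550, -0.556, -0.219 and -0.558 for the ribosomal genes in STIM1KO 1 to 4 and -0.478, -0.444, -0.217 and -0.459 for the proteasome genes, against -0.188 to 0.235 and -0.192 to 0.138 in controls (exact permutation p = 0.0159 for each). The ribosomal genes had a median transcript length of 910 bases, and with the length and GC offsets 24 and 14 members of the lists fell, at medians of -0.19 and -0.23; without number 311 none did, with median log2 fold changes of -0.37 and -0.33. Many ribosomal protein genes share reads with pseudogenes.

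The level of the cytosolic heat shock list was highest in the libraries of number 311, at 0.738 and 0.397, against -0.281 to 0.174 in the other 7 libraries. Hspa1a, an inducible chaperone gene that shares reads with Hspa1b, was at 1207 and 432 CPM in STIM1KO 1 and 2, against 10.8 and 27.1 CPM in STIM1KO 3 and 4 and 5.93 to 138 CPM in controls. Of the 14 genes of the list 0 passed in edgeR, 2 had an unadjusted p under 0.05, DESeq2 called 2 and limma-voom 0. Inhbb, which encodes the beta B subunit of activin and inhibin, was at 31.7 and 30.8 CPM in STIM1KO 1 and 2 and between 5.89 and 9.99 CPM in the other 7 libraries (log2 fold change 1.52 ± 0.45, adjusted p = 0.0559 in edgeR). Slc15a2, a peptide transporter gene, was at 2.56, 8.29, 0.165 and 0.0413 CPM in STIM1KO 1 to 4, the last with 1 estimated count, and at 4.08 to 8.99 CPM in controls; it passed without number 311 and with the number block, and its log2 fold change over all 9 libraries was -1.39 ± 1.00.

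A hypothesis was that Cre at the Ins1 locus removes 1 of 2 Ins1 alleles and so lowers Ins1 against Ins2 by 1 on the log2 scale. The log2 ratio of Ins1 to Ins2 was -2.59 ± 0.407 (SD, n = 5) in controls and -2.75 ± 0.302 (SD, n = 4) in STIM1KO islets, a difference of -0.158 (exact permutation p = 0.556). Against a difference of -1 the exact permutation p was 0.0317. With a library left out it was 0.0286 to 0.0714, and above 0.05 for 7 of the 9 (all but control 1 and STIM1KO 3). The smallest p the test allows is then 0.0286 without a control and 0.0357 without a STIM1KO library. With steps so coarse, a rise above 0.05 says little. The difference ran from -0.319 without control 5 to -0.0222 without STIM1KO 3, with -0.252 without STIM1KO 1 and -0.043 without control 1. The difference was -0.781 within number 789 and 0.325 within number 346, and reads are shared by the genes, so the hypothesis stays open.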
